A study of Mus musculus with 4 samples.

How the data were processed

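The series held 4 retina libraries of mice, 2 from citrate controls and 2 from streptozotocin (STZ) treated animals. Groups came from the sample titles. The table's columns tagged 2L matched a label of their group. The columns tagged 4R named their group but not their sample, since the labels give 4L there, so these were used as further replicates of their group. The column names also carry another time tag than the labels' protocols; the ages given here are the protocols'.

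Per the labels' protocols, polyadenylated RNA was purified from total RNA of dissected retina, made into Ion Torrent whole transcriptome libraries and analysed in Torrent Suite 5.4.0. Reads were aligned to mm10 with STAR, the unmapped reads with Bowtie2, and genes counted with HTSeq and Picard, per the labels' protocols and the submitters' processing notes. The annotation release, the strand setting of the counting and the tool of the authors' comparison are not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical copies such as globins, gamma crystallins, Krt6a and Krt6b, or C4b and its neighbour, therefore cannot be told apart. A signal of gene read counts divided by 1 size factor per library, with the mean over libraries, was deposited by the authors. The authors' deposited table also gave a log2 fold change with its standard error, a test score (the fold change over its error), a p-value and an adjusted p-value for 43280 genes, 18478 of them with an adjusted p.

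The values showed the size factors: 100% of the values in each column were whole multiples of 1 step, to within 0.01 reads. That step, the value of 1 read, was 1.14 normalized counts in control 2L, 1.01 in control 4R, 1.06 in STZ 2L and 0.827 in STZ 4R. In control 4R the step lies too near 1 for the unit check used here to tell it from rounding, so recovery of whole reads was not claimed for that column in the check, and tests on recovered reads serve as alternatives only. The recovered reads came to 29352330 (control 2L), 31973786 (control 4R), 33166680 (STZ 2L) and 39299653 (STZ 4R). At such depths counting error is small for most named genes beside the spread between libraries: the chi-square per degree of freedom was 29.4 between the controls and 255 between the STZ libraries, so within neither group was one library a copy of the other. Shares of reads carry 95% Clopper-Pearson intervals, which cover counting error only.

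Because the unit found was normalized counts, the branch of the design for such values applied. Genes with a value of at least 10 in at least 2 libraries (18127) were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), with a mean-dependent prior, treatment as the only term, all 4 libraries, two-sided tests and Benjamini-Hochberg adjustment at 0.05. The prior added 6.17 degrees of freedom. Fold changes are on the log2(value + 1) scale, which understates changes of low genes, and errors of fold changes are standard errors. The tested genes had a median log2 fold change of -0.01, and other scalings moved it by -0.00 (TMM) and -0.04 (quantile).

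Gene lists were tested with camera in limma, with a preset correlation between genes of 0.01, for lists with at least 3 measured members, adjusted over the 34 lists. The lists covered rod photoreceptors, cone photoreceptors, bipolar cells, retinal ganglion cells, amacrine and horizontal cells, Müller glia, reactive gliosis, microglia and macrophages, endothelial cells, pericytes and smooth muscle, retinal pigment epithelium and melanocytes, lens, red blood cells, cornea and conjunctiva epithelium, skeletal muscle and connective tissue, p53 targets and cell cycle inhibitors, the BCL-2 family, the senescence-associated secretory phenotype, hypoxia, glycolysis, glucose handling and the polyol pathway, antioxidants, interferon response and antigen presentation, complement, oxidative phosphorylation (nuclear and mitochondrially encoded), immediate early genes, the circadian clock, endoplasmic reticulum and amino acid stress, heat shock, basement membrane and extracellular matrix, synaptic transmission, cholesterol synthesis and cytosolic ribosomal proteins. A sex check list was read as values only.

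Named genes followed a fixed rule: with fewer than 10 genes passing, the 10 smallest p values without predicted gene models, said not to pass; up to 4 members of each list with the smallest p; and always Cdkn1a, Cdkn2a, Bcl2l1, Trp53, Vegfa, Gfap, Txnip and Opn1mw. Some genes of the rule are not reported here. Tkt, Krt12 and Cryaa, list members outside that rule, and the mitochondrial ribosome genes of the closing section were named after their values were seen. Groups, tests, lists, naming rule and the alternatives but one were set before the data were examined. The alternatives were a replicate block, each library left out in turn, TMM scaling, quantile normalization, no filter, a filter at 50, pseudocounts of 0.5 and 5, robust moderation, other thresholds, an estimated correlation, fry (which asks whether a list's genes move one way on balance, without comparing them with other genes), and edgeR 4.0.16, DESeq2 1.42.0 and limma-voom on the recovered reads. With 1 library left out, the lone library of its group is assumed to vary like the other group. Without an STZ library, a gene's own spread between the controls carried little weight in limma beside a spread pooled over genes. Crygb, at 221 normalized counts in control 2L and 20.1 in control 4R, still passed there, at 2.08 without STZ 2L. Passing in those fits therefore does not measure a gene's own spread between libraries. An alternative without lens, surface epithelium and the authors' called genes was added after seeing the data. Gene positions come from GENCODE on GRCm38, the assembly also named mm10, and span the whole gene.

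The limma step was tested on simulated data with 2 libraries per group, in 5 runs of 17770 to 17803 genes for STZ against control. It recovered 94 of 344 genes changed 2-fold (27.3%), 257 of 316 changed 4-fold (81.3%) and 323 of 340 changed 8-fold (95.0%), each with the right sign. Over the 5 runs there were 68 false calls. Each simulated gene's spread came from edgeR's estimates, and no gene was simulated as high in 1 library alone. These shares may not carry over to the data, where 0 genes passing does not argue against changes of 4-fold or 8-fold. Of simulated lists shifted by 0.5 log2 units camera called 15 of 15, and of unshifted lists 1 of 155. The simulated genes varied independently of each other. These rates therefore do not cover lists whose genes move together, such as lens, with an estimated correlation of 0.947. For the 52 genes called in the authors' deposited table, DESeq2 on the recovered reads gave log2 fold changes within 2.0e-06 of those listed there.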

Results

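Gene expression was measured by mRNA sequencing in dissected retina of wildtype mice of the strain the labels give as C6/BL6J. The STZ mice had received streptozotocin, a toxin of the insulin-producing beta cells, at 50 mg/kg on 5 days from 6 weeks of age. Control mice received the citrate buffer. Hyperglycaemia above 25 mM was checked 10 days after the injections, and retinas were taken at 18 weeks of age. Each group had 2 libraries, named here by group and by the tag of the table column, 2L or 4R. The reads assigned to genes came to 29352330 in control 2L, 31973786 in control 4R, 33166680 in STZ 2L and 39299653 in STZ 4R. The labels speak of mice but do not state that the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

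The comparison addressed how the retinal transcriptome of hyperglycaemic mice differed from that of controls. Among the single genes with the smallest p, none past the threshold, Aldh3a1, an aldehyde dehydrogenase abundant in cornea, was 14.01-fold higher in STZ on the log2(value + 1) scale, Dsp, the desmosomal protein desmoplakin, 11.4-fold, and Krt6b, an epithelial keratin, 5.62-fold. The reactive gliosis list rose by a median log2 fold change of 0.52 and the complement list by 0.60, while the cone photoreceptor list was lower, at -0.28, as was the bipolar cell list, at -0.19. Each of these 4 calls was made with camera's preset correlation and was lost with an estimated one (camera, adjusted p = 0.468), a form with far fewer degrees of freedom. The cone and bipolar calls were also lost without STZ 2L, at medians of -0.16 and -0.14. The lens list differed furthest of all, at a median of 6.00, and its genes took 9.01% of the reads in STZ 2L (95% Clopper-Pearson interval 8.997 to 9.016, counting error only) and at most 0.0181% in any other library.

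Of 18127 genes tested with limma, 0 passed an adjusted p of 0.05 in either direction, and the smallest adjusted p was 0.135, for Krt6b. At an unadjusted p under 0.05, limma gave 419 higher and 81 lower genes. On the recovered reads, edgeR's quasi-likelihood test passed 0 genes (521 higher and 70 lower unadjusted), limma-voom 0 (317 and 68), and DESeq2 52 higher and 0 lower (554 and 59). The authors' deposited table held 52 higher and 0 lower genes past the same threshold among 18478 genes with an adjusted p, and all 52 were among the 52 that DESeq2 called on the recovered reads. Of those genes in the authors' deposited table, 6 belonged to the cornea and conjunctiva list and 2 to the lens list, and 5 were over 10 times higher in STZ 2L than in STZ 4R. Limma tested 50 of them, and 49 of these 50 had both STZ libraries above both controls. That is largely fixed by their selection as higher in these same libraries. Among all 18127 tested genes, 2599 had both STZ libraries above both controls. Over all tested genes the groups did not overlap in 28.7%, where chance gives 33.3%. Fits with a library left out also change how spread is estimated, since the lone library of a group is assumed to vary like the other group. Their limma counts therefore cannot show whether the result depended on a particular library. With all libraries, the limma count was 13 higher with no filter on low values and 3 higher with robust moderation. It was 0 in both directions (388 higher and 85 lower unadjusted) with lens, surface epithelium and the authors' called genes left out, an alternative chosen after seeing the data.

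The 10 genes with the smallest p, none past the threshold, all lay in both STZ libraries above both controls. Krt6b (chromosome 15, 101676023 to 101680287, mm10) averaged 142 ± 28.1 normalized counts in controls and 797 ± 116 in STZ (SD, n = 2), a log2 fold change of 2.49 ± 0.25 (SE). Aldh3a1 (chromosome 11, 61207537 to 61218421) went from 223 ± 150 to 2839 ± 945 normalized counts (SD, n = 2), 3.81 ± 0.44 on the log2 scale. Its log2 fold change was 4.55 without control 2L and 3.07 without control 4R. Dsp (chromosome 13, 38151294 to 38198577) had a log2 fold change of 3.51 ± 0.45, and Ppl, another protein of epithelial cell junctions (chromosome 16, 5086291 to 5132421), 2.76 ± 0.40. Aqp5, a water channel of cornea and glands (chromosome 15, 99590782 to 99594829), stood at 2.61 ± 0.32, Krt6a at 2.83 ± 0.42 and Adh7, a retinol-oxidising alcohol dehydrogenase, at 3.16 ± 0.47. The protease gene Asprv1, known from skin, stood at 1.67 ± 0.20, the membrane protein gene Mal at 1.76 ± 0.23 and the uroplakin-like gene Upk3bl at 1.95 ± 0.28. Krt6a and Krt6b are near-identical neighbours, so reads may have been split between them. In the authors' deposited table, Krt6b had a log2 fold change of 2.49 with an adjusted p of 5.0e-15 and Aldh3a1 3.67 with an adjusted p of 0.00109. With limma, all 10 passed without STZ 2L (Adh7 had the largest adjusted p, 0.0233) and without STZ 4R (again Adh7, 4.0e-05). Without control 2L, Krt6b (adjusted p = 0.0266), Aldh3a1 (0.000779), Dsp (0.0266) and Krt6a (0.0266) passed in limma, and without control 4R Aldh3a1 (0.0191).

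Of the 34 gene lists, 11 were higher and 8 lower in STZ past an adjusted p of 0.05 in camera with its preset correlation of 0.01, and 12 and 4 after quantile normalization. With an estimated correlation 0 of them held (camera, smallest adjusted p = 0.468), nor did any with fry (smallest adjusted p = 0.628). The estimated form also takes its degrees of freedom from the 4 libraries alone, so a call lost there need not be lost to correlated genes. Glycolysis, with an estimated correlation of -0.02, below the preset 0.01, went from an adjusted p of 0.0455 to 0.468 in camera. Under every omission of 1 library, 5 lists kept their call and direction: cornea and conjunctiva epithelium, lens, basement membrane and extracellular matrix, reactive gliosis, and complement. Over all genes tested 0 members of any list passed in limma. When p was adjusted over the list alone, 11 cornea and conjunctiva genes, 1 matrix gene and 1 complement gene passed, and 0 members of the other 31 lists did.

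The cornea and conjunctiva epithelium list rose, with 12 of 12 measured genes higher and a median log2 fold change of 2.71 (camera, adjusted p = 8.2e-27; adjusted p = 0.468 with an estimated correlation). In limma 11 genes passed when adjusted over the list alone, and all 11 lay in both STZ libraries above both controls. Examples were Aldh3a1, Dsp, Krt6a and Perp, a desmosome-associated protein, at 2.64 ± 0.42. The exception was Tkt (named after its values were seen), a transketolase that retina also expresses strongly, at 0.15 ± 0.22. Without Tkt, these genes took 0.0373% of reads in STZ 2L (0.0366 to 0.0380) and 0.0327% in STZ 4R (0.0322 to 0.0333). In control 2L the share was 0.00597% (0.00569 to 0.00626) and in control 4R 0.00258% (0.00241 to 0.00276). The cornea keratin Krt12, picked out after its values were seen, read 652 normalized counts in STZ 2L, 3715 in STZ 4R, 338 in control 2L and 143 in control 4R. The list's median was 1.70 without STZ 2L, with the call kept (camera, adjusted p between 3.0e-87 and 8.6e-23 over the omissions of 1 library).

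**Figure D1:**
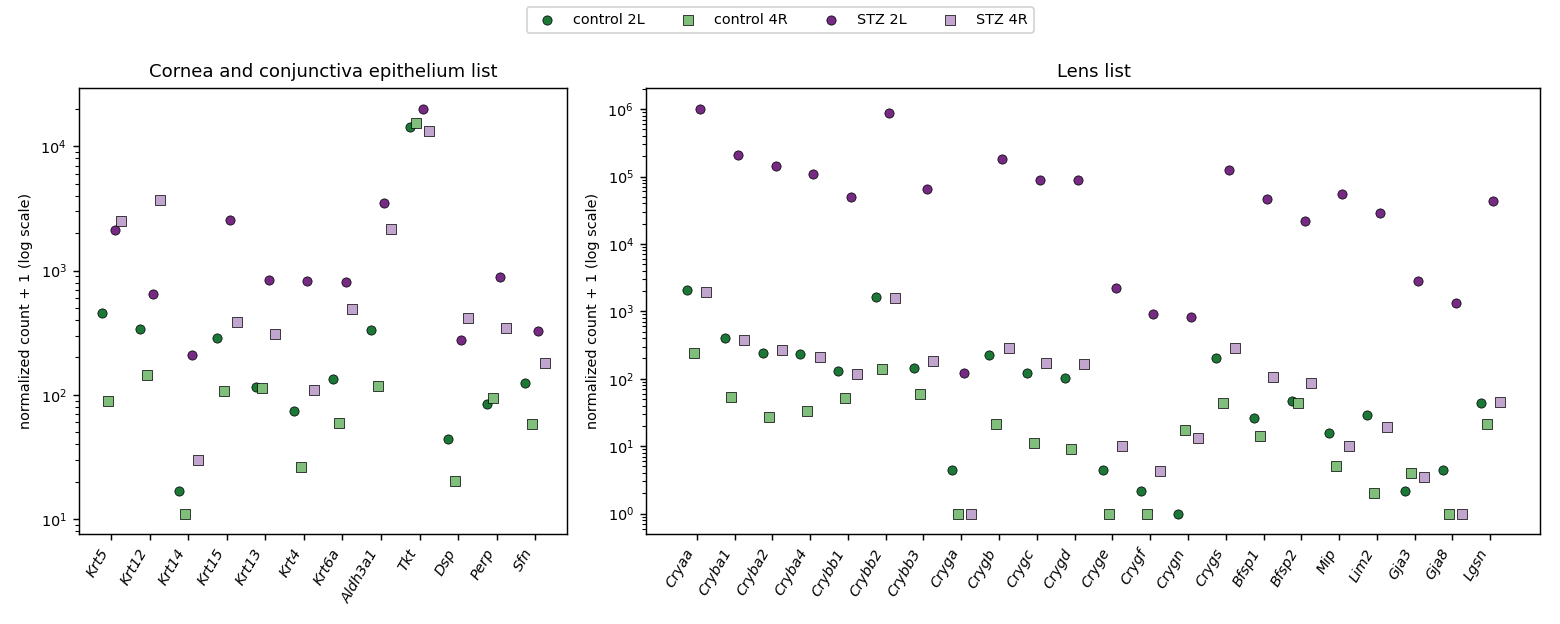
Normalized counts plus 1, on a log axis, of each cornea and conjunctiva gene (left) and each lens gene (right), with 1 point per library and gene. Both STZ libraries lay above both controls for 11 of the 12 surface genes, whereas the lens genes were far higher in STZ 2L alone, where Cryaa reached 1017960 normalized counts against 1945 in STZ 4R.

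The lens list also passed, with 17 of 17 measured genes higher and a median of 6.00 (camera, adjusted p = 5.0e-18; adjusted p = 0.468 with an estimated correlation). Its values came from STZ 2L, where the median lay 10.51 log2 units above the controls, against 1.48 in STZ 4R. Bfsp1, a filament protein of lens fibre cells, had 45743 normalized counts in STZ 2L, 104 in STZ 4R, 25.0 in control 2L and 13.1 in control 4R. Its log2 fold change was 6.84 ± 2.19, and those of the gamma crystallins Crygb, Crygc and Crygd, which share sequence, were 6.72 ± 2.45, 6.73 ± 2.41 and 6.98 ± 2.41. In limma 0 of the 17 passed when adjusted over the list alone, and 14 had an unadjusted p under 0.05. Lens genes took 0.0181% of reads in STZ 4R (0.0176 to 0.0185), 0.0169% in control 2L (0.0164 to 0.0174) and 0.00242% in control 4R (0.00225 to 0.00260). Without STZ 2L the list's median was 1.53 and Bfsp1 stood at 2.46 (limma, adjusted p = 0.0332), and without STZ 4R these were 10.51 and 11.22 (adjusted p = 3.9e-136). Crygb, Crygc and Crygd stood at 2.08, 2.20 and 2.46 without STZ 2L, and at 11.37, 11.26 and 11.51 without STZ 4R. They read 289, 169 and 165 normalized counts in STZ 4R and 221, 122 and 100 in control 2L. In control 4R they read 20.1, 10.1 and 8.05, so their difference without STZ 2L followed the low values of control 4R.

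Reactive gliosis genes, which astrocytes and Müller glia raise after retinal injury, rose as a list in STZ. Of 21 measured genes 20 were higher, 14 of them in both STZ libraries above both controls. The median log2 fold change was 0.52 (camera, adjusted p = 7.3e-11, and 0.468 with an estimated correlation). Among the 14, Timp1 passed the filter on low values through the STZ libraries alone, so its place was fixed in advance. Vim, also among them, is made in lens too, and stood at 0.16 without STZ 2L and 1.98 without STZ 4R. The complement factor C4b (chromosome 17, 34728380 to 34743882) averaged 323 ± 93.5 normalized counts in controls and 685 ± 142 in STZ (SD, n = 2), 1.10 ± 0.27 on the log2 scale. The protease inhibitors A2m and Serpina3n stood at 1.48 ± 0.39 and 2.26 ± 0.69, and Cp, the copper-carrying ferroxidase ceruloplasmin, at 0.52 ± 0.16. Gfap, the intermediate filament used most often to mark gliosis, overlapped between the groups, at 651 ± 144 against 959 ± 353 normalized counts (SD, n = 2) and 0.52 ± 0.28. Limma passed 0 genes adjusted over the list alone, and 8 had an unadjusted p under 0.05. The list's median was 0.42 without STZ 2L, the library rich in lens reads, and 0.40 without control 2L (camera, adjusted p between 8.6e-12 and 5.2e-07 over the 4 omissions). Control 2L read lowest for Serpina3n and A2m: without it they stood at 1.07 and 0.82, against 3.45 and 2.15 without control 4R. In limma, C4b passed without STZ 2L (1.31, adjusted p = 0.00225), while A2m and Serpina3n passed without STZ 2L (1.31, adjusted p = 0.00212, and 1.63, adjusted p = 1.8e-05) and without STZ 4R (1.65, adjusted p = 1.0e-06, and 2.89, adjusted p = 4.6e-20). Gfap stood at 0.91 without STZ 2L, 0.14 without STZ 4R and 0.30 without control 2L. Of the cornea and conjunctiva genes, 11 of 12 lay in both STZ libraries above both controls.

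The complement list rose with 11 of 14 measured genes higher, 7 in both STZ libraries above both controls, and a median of 0.60 (camera, adjusted p = 0.000213; adjusted p = 0.468 with an estimated correlation). C4b was the 1 gene that passed in limma when adjusted over the list alone, and 4 had an unadjusted p under 0.05. The inhibitor Serping1 stood at 0.93 ± 0.28, the central component C3 at 1.23 ± 0.48 and the protease C1ra at 1.45 ± 0.59, all in both STZ libraries above both controls. C4b also belongs to the gliosis list, and C1qa, C1qb and C1qc to the microglia list. Serping1 stood at 0.60 without STZ 2L and passed without STZ 4R (1.26, limma, adjusted p = 0.000924), C3 was 0.68 without STZ 4R, and C1ra was 0.79 without control 2L. In the same libraries 11 of 12 cornea and conjunctiva genes lay in both STZ libraries above both controls, and lens genes took 9.01% of reads in STZ 2L.

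**Figure D2:**
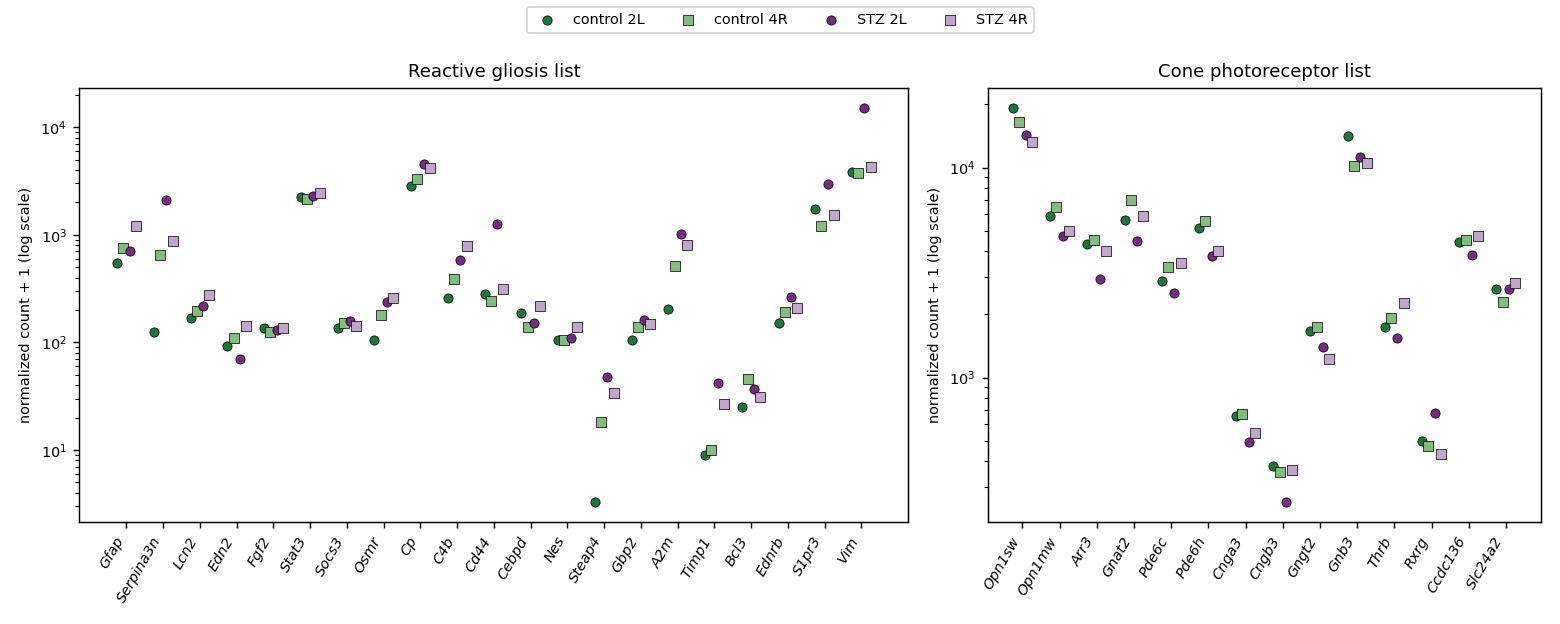
Normalized counts plus 1, on a log axis, of each measured reactive gliosis gene (left) and cone photoreceptor gene (right), with 1 point per library and gene. Both STZ libraries lay above both controls for 14 of the 21 gliosis genes and below both controls for 6 of the 14 cone genes.

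Microglia and macrophage genes did not pass (13 of 20 higher, median 0.11, and 0.21 without STZ 4R; camera, adjusted p = 0.247). Mrc1, a receptor of perivascular macrophages, stood at 1.63 ± 0.70, 0.96 without control 2L, and the homeostatic microglia gene Tmem119 at -0.52 ± 0.38. Müller glia markers did not pass either (9 of 16 higher, median 0.06, 0.033 without STZ 2L and 0.019 without control 4R; camera, adjusted p = 0.156), with Vim at 1.07 ± 0.47, Apoe at 0.29 ± 0.19 and Clu at 0.42 ± 0.28. Vim, an intermediate filament also made in lens, had 15070 normalized counts in STZ 2L and 4250 in STZ 4R, against 3848 and 3781 in the controls. It passed without STZ 4R (1.98, limma, adjusted p = 1.0e-16). Without STZ 2L, Vim stood at 0.16, Apoe at 0.063, Clu at 0.018 and Tmem119 at -0.15, and without STZ 4R Apoe stood at 0.51, Clu at 0.83 and Tmem119 at -0.88. In neither list did a gene pass adjusted over the list alone (0 of each), with 1 microglia and 0 Müller genes at an unadjusted p under 0.05 in limma.

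The basement membrane and extracellular matrix list rose with 19 of 20 genes higher, 13 in both STZ libraries above both controls, and a median of 0.83 (camera, adjusted p = 5.4e-13; adjusted p = 0.468 with an estimated correlation). Tgfbi, a matrix protein abundant in cornea (chromosome 13, 56609523 to 56639562), passed in limma when adjusted over the list alone, at 1.74 ± 0.39. It is also called in the authors' deposited table, at 1.77 with an adjusted p of 0.0464. Col18a1, a basement membrane collagen, stood at 1.36 ± 0.37, the laminin subunit Lamb2 at 0.76 ± 0.24 and the matrix glycoprotein Thbs1 at 0.89 ± 0.29. The median was 1.16 in STZ 2L, the library with 9.01% lens reads, and 0.29 in STZ 4R, so without STZ 2L it was 0.29 (camera, adjusted p = 3.3e-06, the largest of the omissions of 1 library). In limma, Tgfbi passed without STZ 2L (2.01, adjusted p = 0.0158), Lamb2 without STZ 4R (0.94, adjusted p = 0.00514), and Col18a1 without STZ 2L (0.95, adjusted p = 0.00885) and without STZ 4R (1.78, adjusted p = 1.4e-12). Without control 2L, Col18a1 stood at 0.83, Lamb2 at 0.44 and Thbs1 at 0.56. Of the cornea and conjunctiva genes, 11 of 12 lay in both STZ libraries above both controls.

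Genes of the retinal pigment epithelium and melanocytes, which border the retina, were higher in 14 of 15 cases, with a median of 0.75 (camera, adjusted p = 0.000213; adjusted p = 0.560 with an estimated correlation). The difference followed control 2L: they took 0.00869% of reads there (0.00835 to 0.00903), 0.0340% in control 4R (0.0333 to 0.0346), 0.0333% in STZ 2L (0.0327 to 0.0340) and 0.0235% in STZ 4R (0.0230 to 0.0240). Only Ttr, a thyroxine and retinol carrier, lay in both STZ libraries above both controls (0.75 ± 0.38), but it stood at 0.037 without control 2L and 1.46 without control 4R. The melanosome genes Oca2 and Tyrp1 stood at 3.06 ± 1.38 and 1.57 ± 1.04, and the opsin-like gene Rgr at 0.70 ± 0.37. With p adjusted over the list alone 0 genes passed, and 0 had an unadjusted p under 0.05 in limma. Without control 2L the list was lower in STZ, at a median of -0.23 (camera, adjusted p = 0.0261), and without control 4R it was 1.81 (adjusted p = 5.3e-24). Rgr and Oca2 stood at 0.039 and 0.61 without control 2L, and at 1.37 and 5.50 without control 4R. Tyrp1 was -0.23 without control 2L, 3.38 without control 4R and 0.63 without STZ 2L, and, in limma, passed without STZ 4R (2.52, adjusted p = 3.7e-09), as did Oca2 (4.02, adjusted p = 1.3e-06) and Rgr (0.80, adjusted p = 0.0194).

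Cone photoreceptor genes fell as a list: 11 of 14 were lower, 6 of them in both STZ libraries below both controls, with a median log2 fold change of -0.28 (camera, adjusted p = 0.000300; adjusted p = 0.468 with an estimated correlation). Pde6h, the inhibitory subunit of the cone phosphodiesterase (chromosome 6, 136923832 to 136968865), averaged 5344 ± 297 normalized counts in controls and 3893 ± 131 in STZ (SD, n = 2), -0.46 ± 0.15 on the log2 scale. The cone transducin subunit Gngt2 stood at -0.38 ± 0.16, the medium-wavelength opsin Opn1mw at -0.34 ± 0.15 and the short-wavelength opsin Opn1sw at -0.37 ± 0.17. Bipolar cell genes fell too, with 14 of 17 lower, 9 in both STZ libraries below both controls, and a median of -0.19 (camera, adjusted p = 0.000513; adjusted p = 0.468 with an estimated correlation). Pcp2, a G-protein regulator of ON bipolar cells (chromosome 8, 3623371 to 3625545), averaged 7768 ± 346 and 5342 ± 103 normalized counts (SD, n = 2), -0.54 ± 0.15. The transcription factor genes Sebox and Isl1 stood at -0.35 ± 0.20 and -0.26 ± 0.16, and Scgn, a calcium-binding protein, at -0.23 ± 0.15. Limma passed 0 genes of either list adjusted over the list alone, with 2 cone genes and 1 bipolar gene at an unadjusted p under 0.05. Both calls were lost without STZ 2L, at a median of -0.16 for cones (camera, adjusted p = 0.106; 0.00365 to 0.0142 over the other omissions of 1 library) and -0.14 for bipolar cells (adjusted p = 0.0912; 0.00283 to 0.0363), and the bipolar median was -0.10 without control 2L. Sebox stood at -0.57 without STZ 2L and -0.12 without STZ 4R, and Isl1 at -0.16 without control 4R. STZ 2L was the library with 9.01% lens reads, and 11 of 12 cornea and conjunctiva genes lay in both STZ libraries above both controls.

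Rod photoreceptor genes did not pass (16 of 21 lower, median -0.08; camera, adjusted p = 0.108). Pde6g, Rcvrn and Rdh12 stood at -0.42 ± 0.23, -0.29 ± 0.18 and -0.29 ± 0.18. The rod median was 0.06 without STZ 2L and -0.20 without STZ 4R, and Rdh12 stood at -0.19 without STZ 2L, -0.45 without control 2L and -0.12 without control 4R. Smaller shifts passed for amacrine and horizontal cell genes (13 of 16 lower, median -0.09; camera, adjusted p = 0.0395; adjusted p = 0.468 with an estimated correlation) and retinal ganglion cell genes (14 of 16 lower, median -0.09; camera, adjusted p = 0.0428; adjusted p = 0.482 with an estimated correlation). Calb2 and Th, which mark amacrine types, stood at -0.34 ± 0.16 and -0.53 ± 0.28, and the ganglion cell genes Gap43 and Isl2 at -0.32 ± 0.16 and -0.35 ± 0.22. Synaptic genes passed at the threshold itself (17 of 20 lower, median -0.11; camera, adjusted p = 0.0498; adjusted p = 0.693 with an estimated correlation), with Dlg4 at -0.21 ± 0.19 and Cplx3 at -0.20 ± 0.18. Of these lists 0 genes passed adjusted over the list alone, and 0 had an unadjusted p under 0.05 in limma. Each call held only without control 4R among the omissions of 1 library, though not every median shrank. The amacrine and horizontal median was -0.10 without STZ 2L and -0.11 without STZ 4R. In the same omissions the ganglion cell median was -0.11 and -0.07, and the synaptic median -0.04 and -0.12. The medians of the amacrine and horizontal, ganglion cell and synaptic lists were -0.26, -0.17 and -0.26 without control 4R. Without control 2L they were -0.01, -0.04 and -0.02, where the synaptic test turned towards higher. Dlg4 and Cplx3 stood at -0.025 and -0.026 without control 2L and at -0.39 and -0.37 without control 4R, Cplx3 at -0.11 without STZ 4R and Isl2 at -0.19 without control 4R. After quantile normalization all 3 calls were lost (camera, adjusted p = 0.0635, 0.0893 and 0.178), and the synaptic call with TMM scaling (0.0512), no filter (0.0625), a pseudocount of 5 (0.0543) and, chosen after seeing the data, without lens, surface epithelium and the authors' called genes (0.0520). Lens reads were high in STZ 2L alone, and surface epithelium genes in both STZ libraries.

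**Figure D3:**
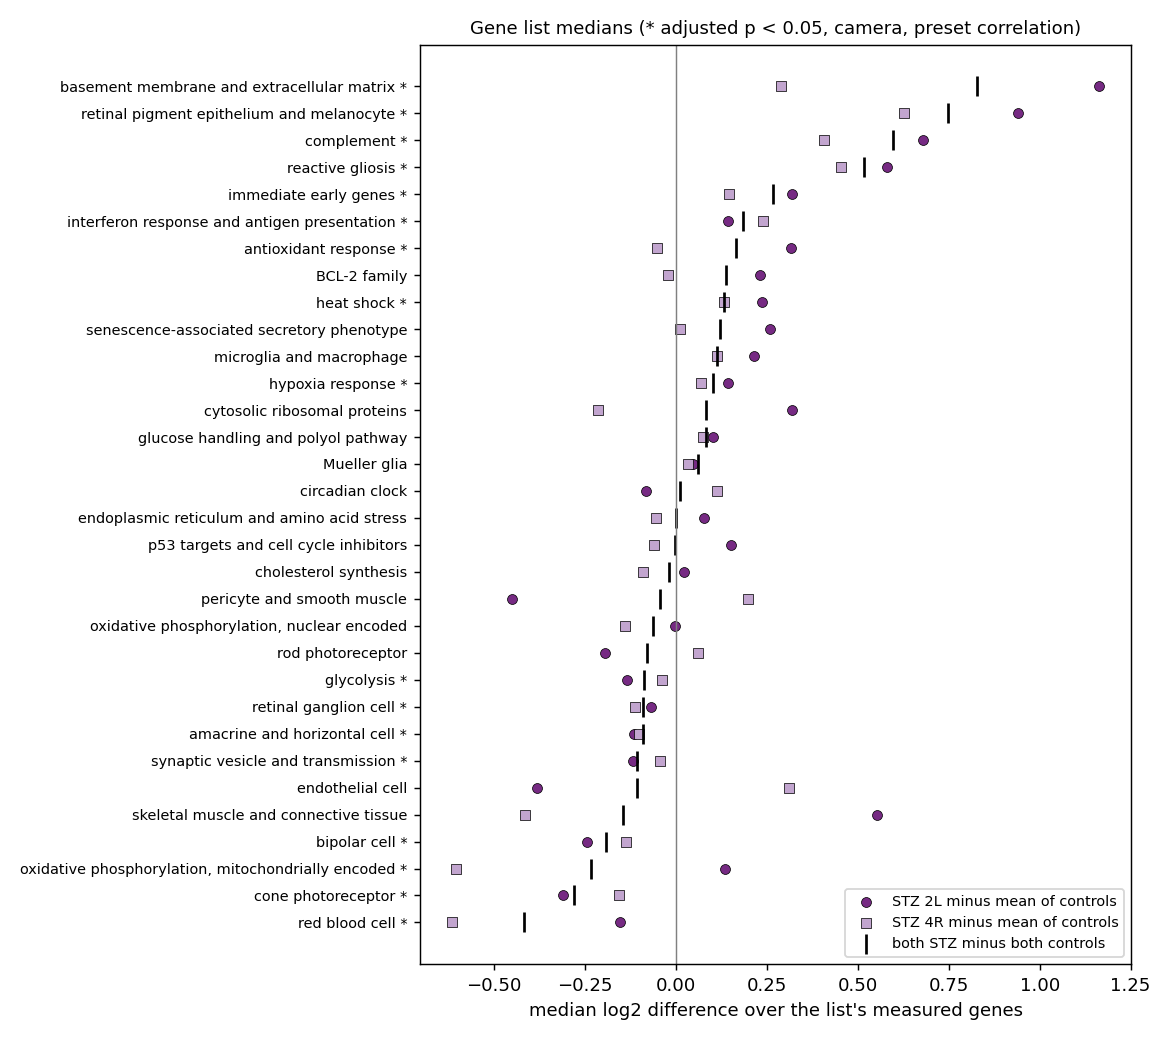
Median log2 difference over the measured genes of each list, other than lens and surface epithelium, for STZ 2L and STZ 4R each against the mean of the controls (points) and for both groups (bars). The gliosis list lay above 0 in STZ 2L (0.58) and STZ 4R (0.45), and the cone list below 0 in both (-0.31 and -0.16).

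Among vascular and other cells, endothelial genes did not pass (11 of 18 lower, median -0.11; camera, adjusted p = 0.247). They went apart between the STZ libraries: without STZ 2L the list was higher, at 0.31 (camera, adjusted p = 0.0325), and without STZ 4R lower, at -0.38 (adjusted p = 0.00672). Mfsd2a, a lipid transporter of the blood-retina barrier, stood at 0.62 ± 0.34 and the adhesion gene Esam at -0.35 ± 0.20. Pericyte and smooth muscle genes did not pass (7 of 12 lower; camera, adjusted p = 0.894), and their median (-0.04) and mean (0.08) differed in sign, the test after quantile normalization pointing lower. The receptor Pdgfrb stood at 0.42 ± 0.21 and the actin Acta2 at 1.90 ± 0.98, which passed without STZ 4R (3.67, limma, adjusted p = 1.5e-26) but stood at 0.14 without STZ 2L, the library rich in lens reads, and 1.15 without control 2L. Mfsd2a and Pdgfrb stood at 0.28 and 0.19 without STZ 2L, and at 0.96 and 0.66 without STZ 4R. Skeletal muscle and connective tissue genes likewise had a median (-0.15) and mean (0.03) of opposite sign and did not pass (7 of 12 lower; camera, adjusted p = 0.914), with the test turning lower after quantile normalization. Col1a2, a collagen chain, stood at 1.51 ± 0.45, and passed without STZ 4R (1.99, limma, adjusted p = 1.2e-06), with 0.90 without control 2L. The red blood cell list passed, with 5 of 5 measured genes lower and a median of -0.42 (camera, adjusted p = 0.0329; adjusted p = 0.560 with an estimated correlation). Hbb-bs, an adult beta globin, stood at -0.69 ± 0.34, and globin copies share reads. It passed in limma without STZ 2L (-0.997, adjusted p = 0.0119), but stood at -0.17 without control 2L, -0.38 without STZ 4R and -1.21 without control 4R. Red cell genes took 0.0165% of reads in control 2L (0.0160 to 0.0170), 0.00613% in control 4R (0.00586 to 0.00641), 0.00849% in STZ 2L (0.00818 to 0.00881) and 0.00570% in STZ 4R (0.00546 to 0.00594). That call was lost without STZ 4R (median -0.15; camera, adjusted p = 0.313) and without control 2L (0.35, adjusted p = 0.249), and the median was -1.21 without control 4R (adjusted p = 1.3e-08). Over these 4 lists limma passed 0 genes adjusted over the list alone, with 1 at an unadjusted p under 0.05, Col1a2. For the sex check, Xist read 1.14 to 8.27 normalized counts and the Y-linked Ddx3y 820 to 1140 over the 4 libraries.

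Among metabolic genes, glycolysis fell slightly as a list, with 15 of 17 genes lower and a median of -0.09 (camera, adjusted p = 0.0455; adjusted p = 0.468 with an estimated correlation). Pgk1 and Tpi1 stood at -0.24 ± 0.15 and -0.24 ± 0.19. That call was lost in each omission of 1 library (camera, adjusted p = 0.255 without STZ 2L, 0.290 without STZ 4R, 0.187 without control 2L and 0.198 without control 4R), and with TMM scaling (0.0511), quantile normalization (0.103), no filter (0.0625) and a pseudocount of 5 (0.0515). The median was -0.038 without STZ 2L and -0.13 without STZ 4R, where Tpi1 stood at -0.41 and -0.079. The 13 measured mitochondrially encoded genes of oxidative phosphorylation were lower in 12 cases, with a median of -0.23 (camera, adjusted p = 0.0153; adjusted p = 0.693 with an estimated correlation), mt-Co2 at -0.29 ± 0.19 and mt-Co3 at -0.23 ± 0.23. This came from STZ 4R and control 2L: the median was 0.13 without STZ 4R (camera, adjusted p = 0.411), -0.00 without control 2L (0.963), -0.60 without STZ 2L (1.3e-14) and -0.48 without control 4R (0.000124). Without STZ 4R, mt-Co2 stood at -0.079 and mt-Co3 at 0.094, and without STZ 2L at -0.49 and -0.56. The nuclear-encoded genes did not pass (20 of 29 lower, median -0.06; camera, adjusted p = 0.134), but did without STZ 2L (-0.14, adjusted p = 0.00742), and had medians of -0.0022 without STZ 4R and -0.020 without control 4R, with Cox7a2 at -0.31 ± 0.17 over all libraries and -0.17 without STZ 4R. Cytosolic ribosomal protein genes did not pass (51 of 78 higher, median 0.08; camera, adjusted p = 0.0620; Rpl39 at 0.53 ± 0.25), and turned with the STZ library: -0.21 without STZ 2L (adjusted p = 1.4e-07) and 0.32 without STZ 4R (1.3e-06). Rpl39 stood at 0.35 without STZ 2L, 0.26 without control 2L and 0.80 without control 4R. The ribosomal list passed without control 4R (median 0.03), after quantile normalization (0.08, camera, adjusted p = 0.00529), with the replicate block (0.0204) and with the stricter filter (0.0457). It also passed without lens, surface epithelium and the authors' called genes (camera, adjusted p = 0.0488), an alternative chosen after seeing the data. Glucose handling and polyol pathway genes did not pass (10 of 15 higher, median 0.08, camera, adjusted p = 0.131). Their median was 0.17 without control 2L and -0.039 without control 4R. Txnip, a glucose-induced inhibitor of thioredoxin (chromosome 3, 96557957 to 96561883), averaged 331 ± 11.3 normalized counts in controls and 583 ± 128 in STZ (SD, n = 2), 0.80 ± 0.23. It had both STZ libraries above both controls and passed without STZ 4R (1.02, limma, adjusted p = 0.0169). Cholesterol synthesis genes did not pass (11 of 18 lower, median -0.02, with the test turning higher after quantile normalization; camera, adjusted p = 0.835; Mvd at -0.22 ± 0.17). For these 6 lists 0 genes passed in limma adjusted over the list alone, with 1 at an unadjusted p under 0.05, Txnip.

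Among stress responses, the antioxidant list rose with 15 of 21 genes higher and a median of 0.16 (camera, adjusted p = 0.00783; adjusted p = 0.604 with an estimated correlation). The cystine transporter Slc7a11 stood at 1.28 ± 0.44, the glutathione transferases Gstm1 and Gsta4 at 1.16 ± 0.48 and 0.61 ± 0.24, and the metallothionein Mt2 at 0.58 ± 0.23. It rested on STZ 2L, the library rich in lens reads: without it the median was -0.05 (camera, adjusted p = 0.758), with Slc7a11 at 0.55 and Gstm1 at 0.25, while without STZ 4R it was 0.32 (1.3e-06) and Slc7a11 (2.01), Gstm1 (2.07) and Gsta4 (0.92) passed (limma, adjusted p = 4.3e-06, 8.5e-15 and 0.00395). Without control 2L the median was 0.07, with the call kept (camera, adjusted p = 0.0372), and without control 4R it was 0.26 (0.0205). Gsta4 stood at 0.31 without STZ 2L. The heat shock list passed with 9 of 12 genes higher and a median of 0.13 (camera, adjusted p = 0.0365; adjusted p = 0.468 with an estimated correlation). Its furthest members, the small heat shock genes Hspb1 (3.10 ± 1.42) and Cryab (3.15 ± 1.60), are abundant in lens, and without STZ 2L they stood at 0.27 and -0.07. Without STZ 4R they passed in limma, at 5.94 (adjusted p = 2.1e-76) and 6.38 (5.9e-113). The heat shock list was not called without STZ 2L, where its median stayed at 0.13, or without control 2L, at 0.064. Its median was 0.24 without STZ 4R and without control 4R. Hypoxia response genes passed with 15 of 23 higher and a median of 0.10 (camera, adjusted p = 0.0182, and 0.495 with an estimated correlation). They were not called without STZ 2L (median 0.068), STZ 4R (0.14, above that of all libraries) or control 2L (0.041). The median was 0.18 without control 4R. Egln3, an oxygen-sensing hydroxylase, stood at 1.15 ± 0.39 and the carbonic anhydrase Car12 at 1.39 ± 0.57 (0.41 without control 2L and 2.38 without control 4R), and both passed in limma without STZ 4R (1.62, adjusted p = 0.00231, and 1.45, adjusted p = 0.0408), with Egln3 at 0.68 without STZ 2L. Vegfa, the vascular growth factor, was at -0.06 ± 0.15, 0.028 without STZ 2L and -0.15 without STZ 4R. Endoplasmic reticulum and amino acid stress genes did not pass (10 of 19 higher, median 0.00; camera, adjusted p = 0.911), with Trib3 at -0.54 ± 0.24 (-0.30 without STZ 4R), nor did circadian clock genes (10 of 18 higher, median 0.01; adjusted p = 0.821), with Nr1d1 at -0.20 ± 0.16 (-0.094 without STZ 2L and -0.31 without STZ 4R). No gene of these 5 lists (0) passed in limma adjusted over the list alone. At an unadjusted p under 0.05 there were 4 antioxidant, 2 hypoxia, 1 endoplasmic reticulum stress, 0 heat shock and 0 clock genes. Beside these shifts, 11 of 12 cornea and conjunctiva genes lay in both STZ libraries above both controls.

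Interferon response and antigen presentation genes rose as a list, with 18 of 22 higher, 10 in both STZ libraries above both controls, and a median of 0.18 (camera, adjusted p = 0.00117; adjusted p = 0.482 with an estimated correlation). Ifit1 stood at 0.99 ± 0.39 and the antiviral tether Bst2 at 0.76 ± 0.32. The call was lost without STZ 4R, at a median of 0.14, and without control 2L, at 0.16. Without control 2L, Ifit1 stood at 0.56 and Bst2 at 0.47. The list's median was 0.24 without STZ 2L and 0.28 without control 4R. Immediate early genes rose with 17 of 22 higher and a median of 0.27 (camera, adjusted p = 0.00258; adjusted p = 0.482 with an estimated correlation), among them Fosl2 at 0.71 ± 0.27 and Klf4, which epithelium also expresses, at 0.91 ± 0.38. That call was lost without STZ 4R, although the median was 0.32 there, and without control 4R, at 0.10. The median was 0.13 without STZ 2L and 0.38 without control 2L. Fosl2 passed without STZ 4R (1.06, limma, adjusted p = 0.0162) but stood at 0.36 without STZ 2L, and Klf4 stood at 0.44 without STZ 4R and 1.38 without STZ 2L. Of the cornea and conjunctiva genes, 11 of 12 lay in both STZ libraries above both controls. In limma 0 genes of either list passed adjusted over the list alone, and 2 of each had an unadjusted p under 0.05.

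Lists bearing on cell senescence and survival did not pass. Of the p53 targets and cell cycle inhibitors, 12 of 24 were higher (camera, adjusted p = 0.435), and their median, -0.00, and mean, 0.12, differed in sign. Cdkn1a, the p21 inhibitor, had both STZ libraries above both controls, at 121 ± 23.3 normalized counts in controls and 190 ± 32.6 in STZ (SD, n = 2), 0.65 ± 0.31. Cdkn2a lay under the filter on low values, at 9.50 normalized counts in STZ 2L, 0.827 in STZ 4R, 3.41 in control 2L and 1.01 in control 4R. Trp53 stood at 0.01 ± 0.21, with its sign turning after quantile normalization (-0.02), without STZ 2L (-0.20) and without control 4R (-0.064), against 0.22 without STZ 4R and 0.086 without control 2L. The senescence-associated secretory list had 20 of 30 measured genes higher and a median of 0.12 (camera, adjusted p = 0.142). That median was -0.044 without STZ 2L, 0.23 without STZ 4R and 0.056 without control 2L. Timp1, a metalloproteinase inhibitor, stood at 1.82 ± 0.60 and Mmp9 at -0.37 ± 0.17. Timp1 passed the filter on low values through the STZ libraries alone, so it was untested when either was left out. The BCL-2 family had 10 of 15 measured genes higher and a median of 0.14 (camera, adjusted p = 0.373), with the survival gene Bcl2l1 at -0.06 ± 0.16 and the death gene Bik at 1.37 ± 0.65. Limma passed 0 genes of these 3 lists adjusted over the list alone, with 1, Timp1, at an unadjusted p under 0.05. Without control 4R, Bcl2l1 stood at -0.18 and the BCL-2 median at -0.10, and without control 2L these were 0.05 and 0.25. Bcl2l1 stood at -0.15 without STZ 2L and 0.018 without STZ 4R.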

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

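The alternative without lens, surface epithelium and the authors' called genes was chosen after the result was seen; the others were not. Over all alternatives, gene results kept their direction and side of the threshold in 2163 comparisons, newly passed in 99 and turned in 17. Of these, 1682, 26 and 1 came from alternatives other than leaving out 1 library. An omission also changes how a gene's spread is estimated, so genes newly passing there do not show dependence on that library. List results kept their direction and side of the threshold in 402 comparisons, no longer passed in 74, newly passed in 8 and turned in 24. Genes passing as higher numbered 13 with no filter (29729 genes tested), 3 with robust moderation and 52 with DESeq2, against 0; leaving out 1 library gave 8 to 551 higher and 0 to 40 lower genes and 7 to 11 higher and 3 to 7 lower lists. Lists passing as lower numbered 4 after quantile normalization against 8, and with an estimated correlation or fry 0 passed as higher and 0 as lower. With the replicate number as a replicate block, 0 genes passed as higher and 0 as lower (476 and 155 at an unadjusted p under 0.05), with 12 lists higher and 8 lower; the list it added was that of cytosolic ribosomal proteins (camera, adjusted p = 0.0204; 1.4e-07 to 0.634 over the omissions of 1 library), and it changed no other list call. The labels name no shared animal or batch, and the 2L libraries' deviations correlated at 0.0988 (Pearson) and 0.151 (Spearman) across genes, which are not independent. These values do not settle a pairing, and the libraries were treated as sharing only a number.

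Quantile normalization turned the test of the pericyte list (median -0.12), the muscle and connective tissue list (-0.26) and the cholesterol list (-0.032), and the sign of Trp53 (-0.019). Fry turned the pericyte list (-0.044) and the endoplasmic reticulum stress list (0.000632). Leaving out 1 library turned these list medians or tests: rod -0.20 to 0.061, endothelial -0.38 to 0.31, pericyte -0.45 to 0.20, retinal pigment epithelium -0.23 to 1.81, red blood cell -1.21 to 0.35, muscle and connective tissue -0.33 to 0.55, p53 -0.065 to 0.17, BCL-2 -0.10 to 0.25, senescence-associated secretory -0.044 to 0.23, glucose handling -0.039 to 0.17 (in these last 2 only the median turned), antioxidant -0.053 to 0.32, mitochondrially encoded oxidative phosphorylation -0.60 to 0.13, clock -0.081 to 0.11, endoplasmic reticulum stress -0.054 to 0.079, synaptic -0.26 to -0.021, cholesterol -0.091 to 0.021 and ribosomal -0.21 to 0.32. It turned these genes: Tyrp1 -0.23 to 3.38, Alas2 -1.25 to 0.018, Hbb-bt -1.11 to 0.35, Hba-a1 -1.29 to 0.46, Cdkn1c -0.082 to 1.61, Sord -0.11 to 0.95, mt-Co3 -0.56 to 0.094, mt-Nd4 -0.72 to 0.11, Phgdh -0.061 to 2.34, Cryab -0.074 to 6.38, Bcl2l1 -0.18 to 0.050, Trp53 -0.20 to 0.22 and Vegfa -0.15 to 0.028. Fewer samples and genes tested are part of these alternatives' construction; beyond that, the cause was not tested. Depth limits genes of few reads, such as Cdkn2a, which stayed under the filter.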

Other observations

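The omissions of 1 library, the estimated correlation and fry were planned for the fixed gene lists, and the general epithelium test was written before its result was seen, while the tests of gene families, the other tests of lens, surface epithelium and glial genes, and the use of omissions to weigh explanations were chosen after the results they bear on. Of 261 gene families named by symbol prefix, 11 passed in camera with its preset correlation, and 0 with an estimated correlation (adjusted p = 0.992 for each of the 11). The 9 higher in STZ were Krt, Tmprss, Anxa, Col, Fzd, Myo, Bmp, Aldh and Itgb, led by the keratins (16 of 20 higher, median 1.42, camera, adjusted p = 1.1e-11). Only Krt (medians 0.96 to 2.34) and Anxa (0.17 to 1.28) passed in every omission of 1 library. The other calls were lost in some omissions, not always with a smaller median. In camera Tmprss (median 1.37 over all libraries, 11 genes) was lost without STZ 2L (0.42, 7 genes) and STZ 4R (0.73, 7 genes). The genes untested there passed the filter on low values through the STZ libraries alone. They were thus bound to be higher in STZ, and the medians cover different genes. Col (0.24) and Aldh (0.082) were lost without control 4R, at 0.016 and 0.13. Bmp (0.31) was lost without STZ 2L (0.11), STZ 4R (0.59) and control 2L (0.35). Myo (0.18) was lost without STZ 4R (0.15), control 2L (0.22) and control 4R (0.16). Fzd and Itgb were lost in each omission, with medians of 0.057 to 0.42 and 0.30 to 0.47. Itgb was lost after quantile normalization too (camera, adjusted p = 0.0569). The 2 lower ones were genes of the mitochondrial ribosome, which translates the mitochondrially encoded messages. Of the large subunit genes 41 of 49 were lower, at a median log2 fold change of -0.11 (camera over 261 families, adjusted p = 0.0163), and of the small subunit genes 22 of 31, at -0.16 (adjusted p = 0.0463). In each family 12 genes had both STZ libraries below both controls, with Mrps11 at -0.46 ± 0.17 and Mrpl34 at -0.38 ± 0.22. Both kept their direction and passed with TMM scaling and quantile normalization, but not without STZ 4R (medians -0.02 and -0.13; camera, adjusted p = 0.914 for both) or without control 4R (-0.10 and -0.09; 0.326 and 0.492). Without STZ 2L the adjusted p was 0.000479 and 0.00659.

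Lens genes were high in STZ 2L. The 7 lens genes that are not crystallins lay a median of 10.48 log2 units above the controls there (SD 1.35 over genes), near the 10.40 of the 15 crystallins, so lens tissue in this library is a candidate source. A crystallin response shared by both STZ libraries is argued against as the cause of the level in STZ 2L, since crystallins in STZ 4R lay a median of 0.12 above the higher control (SD 0.77), with 8 of 15 above it. Against the mean of the controls the lens list did lie 1.48 higher in STZ 4R, and without STZ 2L it passed at 1.53 (camera with its preset correlation, adjusted p = 1.1e-35), with Crygb, Crygc and Crygd passing in limma at 2.08 to 2.46. A smaller difference in STZ 4R, and a response of the STZ 2L retina alone, stay open as untested biology.

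Surface epithelium genes were high in both STZ libraries. Of 34 genes of a general epithelium list, sharing none with the other lists, 25 had both STZ libraries above both controls. Chance gives about 1 in 6 for a single gene, but genes of 1 tissue can move together, so the count does not exclude chance. Esrp2, Lypd3 and Ap1m2 passed the filter on low values through the STZ libraries alone, so their separation was fixed in advance. The list's median log2 fold change was 1.27, so epithelial tissue carried into the STZ samples may be the source. Apart from Tkt, which retina also expresses, the most abundant genes of the surface list in the STZ libraries were Krt12, Aldh3a1, Krt5 and Krt15, at 3715, 3507, 2503 and 2567 normalized counts in the library where each was highest. The ratio of STZ 2L to STZ 4R ran from 0.176 for Krt12 to 7.73 for Krt4, but whether 1 source of fixed composition served both stays open, because the chi-square per degree of freedom over these 11 genes, 555, is set against counting error only and the 2 controls also differed beyond it (29.4 over all genes with at least 10 reads). Dissection cannot be separated from treatment by these libraries, and an effect of STZ on the tissue stays open, untested.

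Reactive gliosis genes were higher in STZ in camera with its preset correlation, a call lost with an estimated correlation (adjusted p = 0.468) and with fry (0.663). Without STZ 2L, the library rich in lens reads, the gliosis list had a median of 0.42 (camera with its preset correlation, adjusted p = 8.7e-12). Without control 2L, low in pigmented tissue, it was 0.40 (adjusted p = 5.2e-07, and 8.6e-12 to 5.2e-07 over the 4 omissions). Passing there cannot argue against lens or pigmented tissue as the cause, because such fits leave a lone library in a group. The lens list also passed without STZ 2L, at a median of 1.53. The gliosis medians show only that neither STZ 2L nor control 2L was needed for the list to lie higher in STZ. Between STZ 4R and control 4R, the libraries left when both 2L libraries are set aside, 19 of 21 genes were higher in STZ, at a median of 0.38 (SD 0.41 over genes). Other tissue differed between these 2 libraries too. Lens genes took 0.0181% of reads in STZ 4R and 0.00242% in control 4R, and surface epithelium genes 0.0327% and 0.00258%. Surface epithelium as the source of these genes cannot be told apart from a glial response. Gfap, the member of the list used to separate them, had a log2 fold change of 0.52 ± 0.28 with overlapping groups. The Müller glia list did not pass, at a median of 0.06 (camera, adjusted p = 0.156). A glial response to hyperglycaemia may underlie the list and stays open, as untested.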
